A study of Mus musculus with 4 samples.

How the data were processed

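The series measured where ARID1A, a subunit of the SWI/SNF chromatin remodelling complexes, sits on the genome of 266-6 cells, a mouse pancreatic acinar cell line, by chromatin immunoprecipitation with sequencing (ChIP-seq). Per the labels, cells grown with 4.5 g/L glucose and 10% serum were starved of serum for about 14 h and then received 40 ng/ml epidermal growth factor (EGF) for 8 h, or 0.1% bovine serum albumin as the control. The labels give 2 libraries for each of the 2 groups. Nothing states that the 2 libraries of a group came from separate cultures. A p-value that compares the groups therefore measures only the spread between these libraries, which may be technical. The other p-values are computed over peaks or over chromosomes and do not measure that spread.

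Per the submitters' processing notes, the work used Bowtie2 2.3.4.2, SAMtools, MACS2 2.1.1.20160309.0 and deepTools 3.0.2 on the mouse build mm9; the options of each step are not given in the sources used here. The authors deposited 1 list of peaks per library, called on that library alone, in the 10 columns that MACS2 writes. Start, end and summit offset are positions as deposited, and are printed counted from 1. The deposited score is 10 times the −log10 q of a peak, rounded down, in 100% of the peaks of all 4 lists. The deposited fold is the ratio of reads at the summit to the local input background, each with 1 added. The deposited −log10 p and −log10 q belong to that same summit. These values are the authors' own for each peak, and they were used to describe, rank and filter peaks within a list.

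The lists give no read totals. Because fold and p come from the same pair of numbers, whole reads at each summit and the local input background could be recovered from them. The fit took 1 scaling factor per library, the Poisson tail of MACS2 and an input background counted in windows of 1 kb and 10 kb for reads extended to 200 bp. A read number was found for 100% of the peaks in each list, with the largest difference from the deposited −log10 p at 9.73e-05. Within a tolerance of 2e-04, each peak had exactly 1 solution. The window sizes and the extension are inferred from the values. The recovered mean was 1.18 and 1.14 ChIP reads per 200 bp of genome in control replicates 1 and 2, and 1.06 and 1.23 in EGF replicates 1 and 2. The input background was 0.771 reads per 200 bp for both control lists and 0.506 for both EGF lists. Fewer input reads scale the ChIP reads down further, to 0.651 and 0.680 per read in the control lists and 0.477 and 0.410 in the EGF lists. The smallest called −log10 p also differed, at 4.43 and 4.25 in the control lists and 7.07 and 8.00 in the EGF lists. At the genome-wide background, these values correspond to 10 and 9 reads in the control lists and 15 and 20 in the EGF lists. The parts of scaling and of p in that difference were not separated. The labels give no batch, and the input depth follows the groups, so it cannot be separated from the treatment. The fewest reads seen at a called summit were 11 and 10 in the control lists and 21 in each EGF list; these are the observed minima, not the numbers a call requires. Intervals given for shares are exact Clopper-Pearson intervals at the 95% level and cover counting error only.

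Peak number and covered length were compared between the groups as log2 ratios of group means, with an exact two-sided permutation test over the 6 assignments of the libraries. Lists were compared by overlaps of at least 1 bp, set against 1000 placements of the peaks at random on their own chromosomes, one-sided. The scores of control peaks also called with EGF were compared with those of the other control peaks by a two-sided permutation test of mean ranks with 100000 resamples. Peaks of 1 library are not independent replicates. The named peaks are the 10 with the highest score in the control list that holds the highest score, among peaks found in both control lists; up to 10 found in both EGF lists, by score; the 3 with the highest score in each EGF list; and the 5 highest control peaks found in both control lists and in no EGF list. The comparisons, tests, named-peak rule and alternatives were fixed before the data were examined, apart from those said to be chosen later. The recovery of reads, the values that rest on it and the comparison of chromosomes were chosen after the data were seen. The alternatives were a stricter q of 0.005, merging of peaks within 500 bp, leaving out contigs and the X chromosome, other definitions of overlap, ranking by width, a block on the replicate number, and leaving out each library in turn.

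Gene assignment, genomic location, gene list enrichment and motif searches had been planned and were not run, because the reference used here is an annotation of another build, GRCm38.p6, with no sequence, and coordinates were not converted. That annotation served only to check the build. In control replicates 1 and 2, 5.33% and 5.72% of peak midpoints lay within 1 kb of the end of a protein-coding gene at face value, against at most 4.74% and 5.01% after 10 shifts of the coordinates by 20 kb to 2 Mb, while 25 and 42 peaks lay beyond the last gene of their chromosome. In the same lists, 2 and 3 peaks lay on contigs of mm9. The shares near gene ends alone lean slightly towards the annotation, while the peaks beyond the last gene and on contigs go with mm9. The build in the processing notes was kept, and peaks are named by position.

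Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The steps were tested on simulated data. In lists of 4031, 7112, 57 and 20 simulated peaks, 100% of the read numbers were recovered. Of 1209 overlaps planted in a list the size of control replicate 1, 100% were found. In the rank test on 4031 ranks, 7.5% of 200 random choices and 100% of 200 planted shifts passed a threshold of 0.05. In the correlation test over 20 values, 5.5% of 200 unrelated sets and 100% of 200 planted relations passed it.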

Results

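ARID1A peak lists of 266-6 acinar cells were compared between cells given EGF, a growth factor that signals through its receptor tyrosine kinase, and control cells given albumin, with 2 libraries per group. The question set by the design is how EGF changes the places that ARID1A occupies. The ChIP depth recovered from the lists was alike in the groups, at 1.16 ± 0.0346 reads per 200 bp of genome in the control group (SD, n = 2) and 1.15 ± 0.121 in the EGF group (SD, n = 2). The lists were called against an input background of 0.771 reads per 200 bp in the control group and 0.506 in the EGF group, and the fewest ChIP reads seen at a called summit were 11 and 10 in the control lists and 21 in each EGF list. All positions are in mm9, and no gene was assigned to a peak.

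In control cells, ARID1A peaks were found on every autosome and on the X chromosome, and most of the peaks of the smaller control list were found in the other. Of the 4031 peaks of control replicate 1, 2874 (71.3%, interval 69.9% to 72.7%) overlapped a peak of control replicate 2, against 0.226% for random placement (permutation p = 0.001, the smallest that 1000 placements can give). In the other direction, 2871 of 7112 peaks (40.4%) were shared. The 100 peaks with the highest score in each control list were all present in the other one. Peaks shared by both control lists had a median fold of 6.08 and 6.62 in control replicates 1 and 2, and unshared peaks 5.38 and 5.51. Across the 2874 shared peaks, which are not independent replicates, log2 fold correlated with r = 0.518 between the control lists, and the difference between them had an SD of 0.38.

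Control peaks were spread unevenly over the chromosomes. Chromosome 15 had the densest peaks, with 3.15 and 5.66 per Mb in control replicates 1 and 2, and the X chromosome the sparsest, with 0.150 and 0.270. Chromosomes 10 and 11 followed chromosome 15, with 2.80 and 4.63 per Mb on chromosome 10 and 2.48 and 4.78 on chromosome 11, while chromosome 18 had 0.807 and 1.36. The input background recovered at the peaks differed as well, at a median of 2.59 times the genome-wide background on chromosome 15 and 1.04 and 1.01 times on chromosome 18. On the X chromosome this median was 1.30 times in both control lists, above chromosome 18 although X had sparser peaks. It was raised by the X peaks between 160 and 170 Mb, whose own median was 9.75 and 8.30 times in control replicates 1 and 2. Over the 20 chromosomes, this median and the peaks per Mb correlated with Spearman rho = 0.866 and 0.869 (permutation p = 1e-05 in each, the smallest possible) and Pearson r = 0.729 and 0.760 (permutation p = 4e-05 and 1e-05). Adjusted by Benjamini-Hochberg over the 6 relations computed, these were 2e-05 for both rho, and 8e-05 and 3e-05 for r; without chromosomes 5 and 15, r was 0.745 and 0.781. Among peaks with at least 10 times as many reads as the local input, chromosome 15 was not the densest, at 0.985 and 0.927 times the density of the median chromosome against 2.21 and 2.27 times for all peaks. For those peaks r was 0.243 and 0.221 (permutation p = 0.28 and 0.33, adjusted 0.33 for both), rising to 0.608 and 0.634 without chromosomes 5 and 15, and rho was 0.656 and 0.660 (permutation p = 0.0021 and 0.002, adjusted 0.0021 for both).

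**Figure D1:**
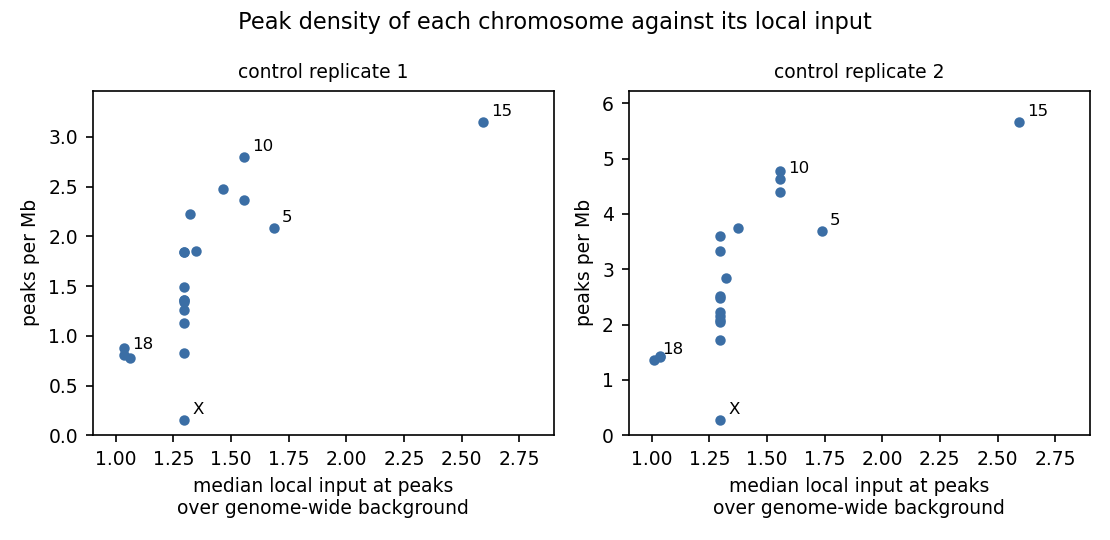
Each point is 1 of 20 chromosomes in control replicate 1 (left) or 2 (right), with the median local input at its peaks over the genome-wide background on the x axis and its peaks per Mb on the y axis. All peaks are counted; chromosome 15 lies highest on both axes, at 2.59 times the background, but had 0.985 and 0.927 times the density of the median chromosome for peaks with at least 10 times the local input, which are not plotted.

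Ranked by score in control replicate 2, the strongest peak found in both control lists lay at 15:36209486-36209951, with a deposited fold of 20.4 in control replicate 1 and 23.0 in control replicate 2. The peak at 15:62423329-62424398 followed, with 15.3 and 17.5, and the one at 4:51487939-51488540, the highest by score in control replicate 1, had 25.9 and 22.8. The peak at 5:89981912-89982594 differed more between the replicates, with 12.7 and 22.0. The peak at 15:56928213-56929276 had a fold of 15.9 and 17.7. Next by score were 5:50306998-50307455 with 12.9 and 16.6, and 10:53778771-53779343 with 12.0 and 16.8. Each of these 7 peaks was called in at least 1 EGF list. The remaining 3 of the 10 strongest by that score lay at 16:80272449-80273335, 3:53362894-53363466 and 1:52053429-52054098, and none of those 3 was called with EGF.

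**Figure D2:**
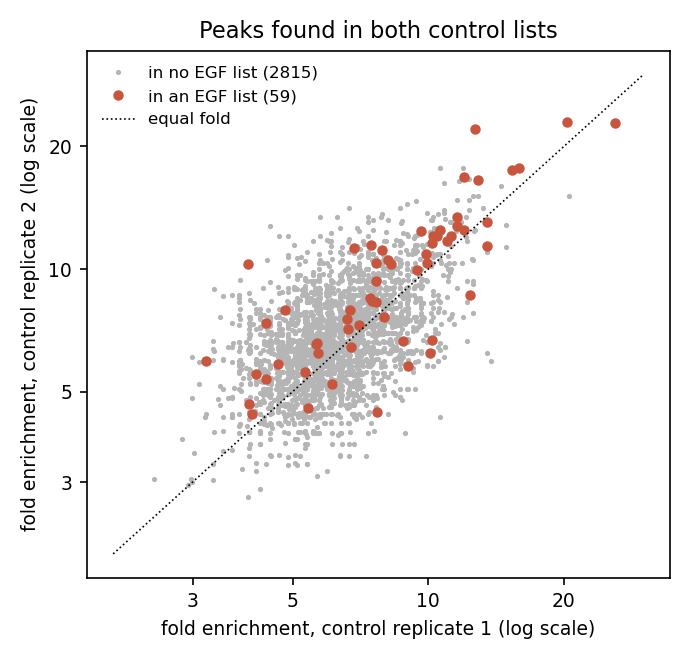
Each point is 1 of the 2874 peaks found in both control lists, with its deposited fold enrichment in control replicate 1 on the x axis and in control replicate 2 on the y axis, both on log scales. Red points mark the 59 that overlapped a peak of an EGF list, grey points the 2815 that did not, and the dotted line is equal fold.

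With EGF, nearly all ARID1A peaks were missing from the lists. EGF replicates 1 and 2 held 57 and 20 peaks, against 4031 and 7112 in control replicates 1 and 2. The mean fell from 5572 ± 2179 peaks in the control group to 38.5 ± 26.2 in the EGF group (SD, n = 2 each), 145-fold fewer (log2 ratio −7.18). The smaller control list held 70.7 times as many peaks as the larger EGF list. The length under peaks was 1332 and 2407 kb in the control lists and 13.9 and 5.06 kb in the EGF lists, 197-fold less (log2 ratio −7.63). The EGF peaks were narrower, with a median width of 224 and 238 bp against 288 bp in each control list. Number, length and width all depend on the input depth and the p-values at which peaks were called, which differed between the groups. At the settings of the EGF lists, 22.2% to 34.8% of the peaks of a control list still passed. The narrower width was not separated from these settings.

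The groups did not overlap in either measure, and the exact two-sided permutation p was 0.333 for both, the smallest that 2 libraries against 2 can give, so the design cannot reach 0.05. Without EGF replicate 1 the differences were 279-fold in number and 370-fold in length, and with 1 p-value bound in all lists, chosen after the data were seen, the difference in number was 91.6-fold.

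**Figure D3:**
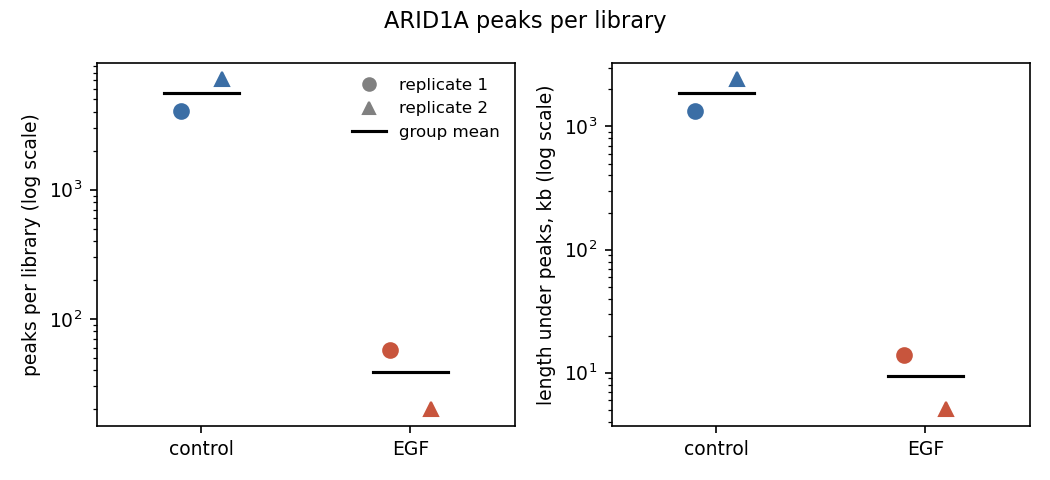
Points are libraries (circles replicate 1, triangles replicate 2) and lines are group means, for the number of peaks on the left and the length under peaks in kb on the right, both on log scales. The control libraries hold 4031 and 7112 peaks and the EGF libraries 57 and 20.

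The few peaks called with EGF lay where control cells also had peaks. Of the 57 peaks of EGF replicate 1, 56 overlapped a peak of each control list, and all 20 peaks of EGF replicate 2 did so. Merged, the EGF lists gave 61 regions, of which 59 (96.7%, interval 88.7% to 99.6%) were in both control lists, against 0.00164% for random placement (permutation p = 0.001, the smallest possible). Random placement does not allow for the local input. At the 60 of these regions called in each control list, it was at a median of 2.20 and 1.96 times the genome-wide background in control replicates 1 and 2. The p therefore does not separate shared ARID1A sites from places of high input. The region 10:26548633-26548838 was called in control replicate 1 alone of the controls, the region 4:43543195-43543404 in control replicate 2 alone, and 0 regions were in neither. Both were named after their values were seen. Of the 20 peaks of EGF replicate 2, 16 (80.0%, interval 56.3% to 94.3%) were also in EGF replicate 1, against 0% for random placement (permutation p = 0.001). When 50% of both peaks had to be shared, 17 of the 61 regions (27.9%) were still in both control lists (permutation p = 0.001), the EGF peaks being narrower.

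Conversely, few control peaks were called with EGF. Of the 2874 control peaks found in both control lists, 59 (2.05%, interval 1.57% to 2.64%) overlapped an EGF peak. The share was 0.696% without EGF replicate 1 and 0.844% without control replicate 1, and 1.21% when 50% of both peaks had to be shared. These shares also count control peaks too weak to pass at the read scaling, input depth and smallest called −log10 p of the EGF lists. Ranked by score in control replicate 2, the 5 highest shared control peaks absent from both EGF lists were 16:80272449-80273335, with a fold of 14.5 and 16.0 in control replicates 1 and 2, 3:53362894-53363466 with 12.0 and 17.7, 1:52053429-52054098 with 10.6 and 17.7, 16:57569112-57569493 with 11.7 and 16.5, and 3:57148208-57148699 with 12.3 and 16.7.

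At the 16 sites called in all 4 libraries, the direction of the difference depended on the scaling. Divided by the genome-wide mean of its library, the reads at the summit were at a median of 0.807 times the control mean with EGF (log2 −0.31), from 0.429 to 1.41; divided by the local input, a scaling added after the data were seen, they were at a median of 1.34 times (log2 0.42), from 0.364 to 3.26. By the genome-wide mean, both EGF libraries lay below both control libraries at 10 sites, at 1 of them by less than the rounding, and above both at 3. By the local input they lay below both at 5 sites and above both at 8. The genome-wide input background was the same in both lists of a group, at 0.771 in the control lists and 0.506 in the EGF lists. This goes with 1 input shared by the lists of a group. The libraries of a group are then not separate measures of the input. If the libraries could be exchanged, chance would give 16.7% of sites in each direction. The sites were chosen by being called with EGF and the inputs differ between the groups, so the counts cannot be read against that share.

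Both scalings put the EGF libraries below the control libraries at 5 sites. The site at 15:36209600-36209838 went from 63.9 ± 5.58 times the genome mean in control cells to 27.4 ± 1.43 with EGF (SD, n = 2 each), 0.364 times by local input. The strongest site of EGF replicate 1, at 15:62423653-62424014, went from 77.2 ± 4.15 to 54.0 ± 7.53, the site at 15:56928922-56929160 from 50.9 ± 3.97 to 36.0 ± 2.99, and that at 5:89982077-89982398 from 38.6 ± 15.2 to 19.6 ± 0.216. The fifth lay at 10:110485057-110485318.

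Both scalings put the EGF libraries higher at 3 sites. The summit at 15:64729937-64730206 had 21.5 ± 5.45 times the genome mean in control cells and 30.2 ± 2.56 with EGF, the one at 5:42867890-42868111 had 21.2 ± 2.46 and 27.2 ± 5.15, and the one at 19:53478717-53478960 had 30.2 ± 3.35 and 35.2 ± 1.84. At some of the other sites the scalings differed. At 11:67905574-67906001 the values over the genome mean were 46.2 ± 5.66 and 30.4 ± 1.73, lower with EGF, while those over local input were 8.14 and 9.68 in control replicates 1 and 2 and 23.8 and 25.8 in EGF replicates 1 and 2. The local input there was 4.0 reads per 200 bp in both control lists and 0.62 in both EGF lists, so the replicates do not show its spread. The means at 10:56767550-56767842, 15:30215348-30215620 and 16:85887724-85888099 were likewise 0.797, 0.776 and 0.606 times the control mean by the genome-wide scaling and 2.07, 1.71 and 1.99 times by the local input. At 5:13477622-13477907, with 34.0 ± 4.47 and 29.0 ± 4.28 times the genome mean, and at 10:107366836-107367199, the means were lower with EGF by both scalings, at 0.853 and 0.845 times control by the genome mean and 0.891 and 0.789 by local input, but the libraries of the groups overlapped. These sites were chosen by being called with EGF, and single sites were not tested. The peak at 13:54526706-54526958, among the 3 strongest of EGF replicate 1 with a fold of 12.4, was not called in EGF replicate 2, and had 13.5 and 11.4 in the control lists.

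**Figure D4:**
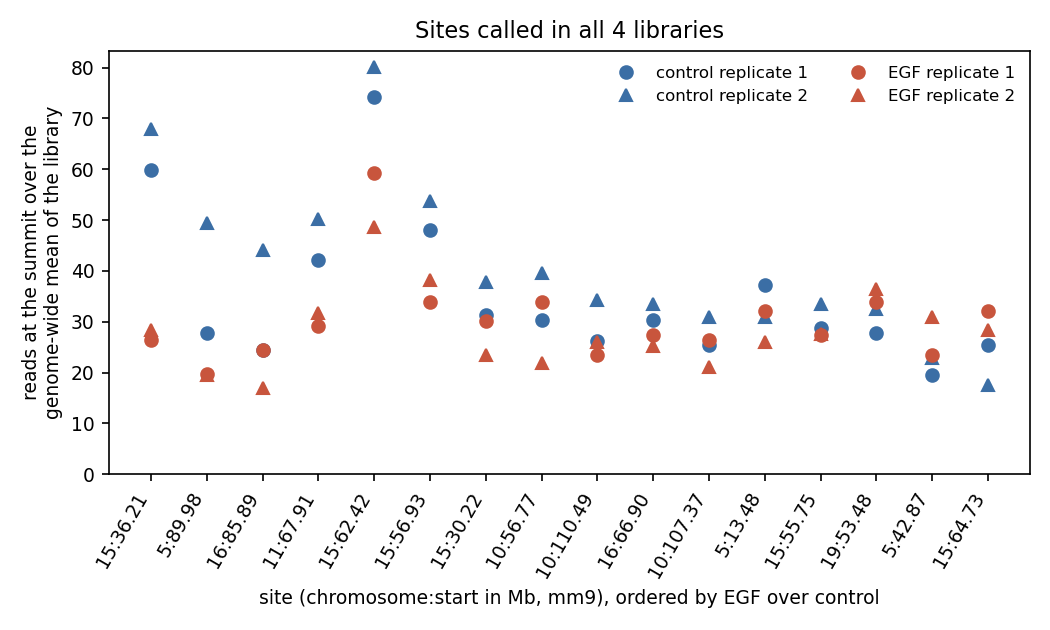
For each of the 16 sites called in all 4 libraries (x axis, chromosome and start in Mb, ordered by the ratio of the EGF mean to the control mean), points give the reads at the summit over the genome-wide mean of the library (y axis) in the 2 control libraries (blue) and the 2 EGF libraries (red). The ratio runs from 0.429 on the left to 1.41 on the right; over local input, which is not plotted, its median is 1.34.

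The control peaks that were also called with EGF ranked high among control peaks, but they were not simply the highest. Their mean score percentile was 82.5 in control replicate 1 and 89.6 in control replicate 2, with 60 such peaks in each list and a mean of 86.1 (permutation p = 1e-05, the smallest that 100000 resamples can give). The median score of these peaks was 120.5 against 47.0 for the other peaks of control replicate 1, and 139.5 against 46.0 in control replicate 2. Of the 50 highest peaks, 13 in control replicate 1 and 9 in control replicate 2 were called with EGF. Among the 60 called with EGF, 9 in control replicate 1 and 2 in control replicate 2 lay below the median score of their list. The peak at 4:51487939-51488540, the highest of control replicate 1 with 69 reads at its summit, was called in EGF replicate 1 with 36 reads and not in EGF replicate 2.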

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

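Leaving out chromosome 15, using 1 p-value bound in all lists, ranking by fold or by recovered reads, and scaling summit reads by local input were chosen after the data were seen; the other alternatives were planned. Of 46 alternative values for 8 results, 41 kept their direction and their side of the threshold or stayed within the interval, 4 moved, all in the share of control peaks also called with EGF, and 1 reversed. The median log2 ratio of summit reads at the 16 sites called in all 4 libraries was −0.31 over the genome-wide mean and 0.42 over the local input, which was lower relative to its background in the EGF lists. The share of control peaks also called with EGF was 2.05%; it was 1.21% when 50% of both peaks had to be shared, and 0.696% to 1.91% with each library left out in turn, since each omission changes the lists the share is counted on. The log2 ratio of peak number ran from −8.12 to −6.52 over its 10 alternatives and that of covered length from −8.53 to −7.07. These alternatives are among the 41 and were judged by sign alone, which differences of this size could hardly change. With 2 libraries per group no p under 0.333 can arise, so the tests of number and length say nothing about stability, and ratios with a library left out are values with no test. The number of peaks was 176-fold lower without chromosome 15 and 91.6-fold lower with 1 p-value bound. The overlap of the control lists ran from 55.3% to 75.0%, that of the EGF lists from 75.0% to 80.0%, and the mean score percentile of retained peaks from 76.5 by fold to 91.4 by recovered reads. The share of EGF regions in both control lists was 27.9% with 50% of both peaks shared and at least 96.5% under the other 6 alternatives. The 27.9% is also among the 41, because only its side of the threshold against random placement was judged. With the replicate number as a block, the log2 ratios were −7.31 for number and −7.74 for length (exact permutation p = 0.5, the smallest for 2 pairs); the libraries share only a number, and at the 16 sites called in all 4 libraries the deviations of same-numbered libraries correlated at r = −0.0893. Alternatives for genomic location, gene lists and motifs were not run. At the genome-wide background, the smallest called −log10 p corresponds to 10 and 9 reads in the control lists and 15 and 20 in the EGF lists. It belongs to the weakest peak of each list and is not the bound of the call, which is not given. The −log10 q of that peak was 1.31 and 1.38 in the control lists but 2.07 and 2.47 in the EGF lists. Since the EGF lists were called on a shallower input, a site absent from them is not shown to lack ARID1A.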

Other observations

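The tests of read depth and of DNA copy number, the ratio of reads to local input, the input at the EGF sites, and the descriptions of chromosomes and clusters were chosen after the results were seen.

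Chromosome 15 held 8.06% and 8.21% of the peaks of control replicates 1 and 2, but 11 of 57 and 8 of 20 peaks of EGF replicates 1 and 2. Of the 263 peaks on chromosome 15 shared by both control lists, 13 (4.94%) were called with EGF, against 1.76% elsewhere (Fisher's exact test p = 0.00202, adjusted p = 0.0404 by Benjamini-Hochberg over 20 chromosomes). The test counts peaks of the same libraries as if they were independent, which they are not. No other chromosome had more than 6 shared control peaks called with EGF, too few for such a test to show much. On each of the other chromosomes the adjusted p was 1. The local input at control peaks on chromosome 15 was also the highest of all chromosomes, at a median of 2.59 times the genome-wide background in both control lists, and reached 3.63 and 3.85 times between 60 and 70 Mb, where the strongest peak of EGF replicate 1 lies. The X chromosome held 25 and 45 control peaks, of which 11 in each list lay between 166412097 and 166446920, where the local input reached 20.7 times the genome-wide background. No EGF peak lay on the X chromosome, nor on chromosomes 12 and 18. X held only 17 shared control peaks, too few to show a difference from the 2.05% called with EGF among all shared control peaks.

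Few groups of neighbouring control peaks were large, but the grouping that random placement would give was not computed. The 2871 peaks of control replicate 2 shared with control replicate 1 formed 2508 groups when peaks within 12.5 kb were joined, 2213 of them single peaks, and 5 groups held at least 5 peaks. Besides the group at the end of the X chromosome, these lay at 15:58857242-58887093, 10:92732312-92739597, 10:110987267-111013408 and 11:57767177-57787662. None of the 29 peaks in those 5 groups was called with EGF, a number too small to show a difference from the 2.05% of all shared control peaks. The highest local input of any control peak was at 11:3046846-3048014 in control replicate 2, at 38.9 times the genome-wide background and with a fold of only 3.06.

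The first pattern is the small number of ARID1A peaks with EGF. The recovered depth argues against fewer reads in the EGF ChIP libraries, since their mean per 200 bp was 0.99 times that of the control libraries. Control peaks were recomputed at the read scaling, input depth and smallest called −log10 p of each EGF library. They still numbered 24.3 to 81.3 times the EGF peaks, which argues against a shallower input and a stricter p-value bound as the whole cause. The control peaks that passed were 34.3% and 34.8% of control replicates 1 and 2 at the settings of EGF replicate 1. At those of EGF replicate 2 they were 22.2% and 22.9%. The other control peaks would not have passed, so the settings may account for part of the difference in number. A weaker immunoprecipitation in both EGF libraries may account for it and stays open, since the sites with a value for it (16, with enrichment over input higher with EGF at a median log2 ratio of 0.42, SD 1.03, where reads over the genome mean were lower at −0.31) were chosen by being called with EGF, and their local input was 2.59 and 2.98 times the background in the control lists and 1.98 in each EGF list. A loss of ARID1A from its sites after EGF, the difference the design names, is equally open and cannot be told apart from it, because both follow the groups.

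The second pattern is the uneven density of control peaks over the chromosomes, highest on chromosome 15 and lowest on X. DNA copy number, as the local input shows it, goes with density over the chromosomes as a set, with rho at 0.866 or more in both control lists. Input at peaks can also rise in open chromatin. By its median input the X chromosome departs from the relation, at 1.30 times the background in both lists, above chromosome 18, where peaks were denser. That median includes the 11 of 25 and 11 of 45 X peaks in the stretch of high input at the end of X. Outside 160 to 170 Mb, no 10 Mb stretch of X had a median above 1.15 times in control replicate 1 or 1.30 times in control replicate 2. The departure therefore rests largely on the end of X, and the other X peaks do not show it. Whether more copies only make calling easier stays open: among peaks whose fold would be called at the lowest background, rho was 0.834 and 0.852, over the bound set against that explanation, but the bound was wrong because the deposited fold adds 1 to both parts and so rises with input at an unchanged ratio. For peaks with at least 10 times as many reads as the local input, the density of chromosome 15 was 0.985 and 0.927 times that of the median chromosome, against 2.21 and 2.27 for all peaks, which goes with easier calling, but rho was 0.656 and 0.660 (permutation p = 0.0021 and 0.002; 0.752 and 0.808 without chromosomes 5 and 15), which goes against it as the whole cause, and r was 0.243 and 0.221 (0.608 and 0.634 without them). That rho does not settle it, because the input background never falls below the genome-wide value (it was above it at only 57.4% and 50.4% of the peaks on chromosome 18), so the ratio can be understated where copies are few; no biological explanation was tested.

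The third pattern is that the peaks called with EGF were mostly strong control peaks but not simply the strongest: of 60 in each control list, 30 and 35 lay in the top 5% by score in control replicates 1 and 2, while 37 and 41 of the 50 highest were not called with EGF. If every site were lowered by the same factor, with counting noise, 100 simulated draws gave mean score percentiles of 90.0 to 95.4 for control replicate 1, and the observed 82.5 differed from the nearest draw by −7.51. For control replicate 2 the draws gave 90.7 to 97.6 against 89.6. The draws rest on an assumed background at each site and exclude nothing, so an equal lowering stays open beside a change that may differ between sites.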
